A study of Homo sapiens with 4 samples.

How the data were processed

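The series holds single-cell RNA sequencing of CHP134 cells treated for 24 h with DMSO (0.04%), 13cRA (5 µM), doxazosin (10 µM) or both drugs, with 1 sample for each treatment. Per the labels, the 4 cell suspensions were dispensed on 1 ICELL8 chip, wells with single live cells were chosen by imaging, and full-length libraries without molecular identifiers were made with SMARTer chemistry. The deposited table holds raw read counts per gene and cell, in whole numbers, for 60651 versioned Ensembl gene IDs and 1287 cells, and column names tie every cell to its sample. The submitters' processing notes list bcl2fastq, fastp 0.23.3, STAR 2.7.8a, featureCounts and Seurat 4.3.0, and the builds GRCh38.p13 and GRCh37 with no role given to either. The annotation release, the strandedness of the counting, its treatment of reads shared between genes and the authors' filters are not given in the sources used here. Antisense genes and near-identical paralogs (CKMT2-AS1, SCAMP1-AS1, ANKRD36C, HSPA1B) are uncertain for that reason.

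Cells with at least 500 detected genes and at most 25% of counts from mitochondrially encoded genes were kept: 1197 of 1287 cells, with 21 below the gene minimum and 70 above the mitochondrial maximum, 1 of them on both grounds. No doublet caller was run, since wells had been chosen by imaging; 5 cells had over 9000 genes, the highest 18592. Of the gene IDs, 60481 matched a symbol and 170 did not, and 784 IDs with counts carried a symbol that another ID already held and were kept under their ID. A count was seen for 52040 genes. Gene positions and GC content come from GENCODE 29 on GRCh38, which is the annotation at hand and is not known to be the one behind the counts.

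Counts of the kept cells were summed per sample and scaled to CPM over all genes. Differences are log2((CPM + 1)/(CPM + 1)) of the 2 samples compared, with a pseudocount of 1 CPM. The comparisons were each treatment with DMSO, the combination with each single drug, and the departure from additivity (combination minus 13cRA minus doxazosin plus DMSO). No p-value, standard error or count of changed genes was computed, because each treatment has 1 sample and cells of a sample are not replicates. Each CPM has an exact 95% Poisson interval of its summed count, and each share of cells an exact (Clopper-Pearson) 95% binomial interval. Reads amplified without molecular identifiers are not independent molecules, so the intervals of a CPM, and the limit of 3 counts that a count of 0 allows, cover counting error only. Those of a share cover only the sampling of cells. Total counts per sample ranged from 22636509 to 72192743.

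Before the data were examined, 26 gene lists were fixed, 21 for pathways and cell states and 5 for markers of other cell types (Schwann cell, fibroblast, leukocyte, endothelial and epithelial). The median log2 difference was taken over members with at least 5 CPM in at least 1 of the 2 samples and given as a percentile among 10000 random lists of the same size, matched in 20 bins of mean CPM; the percentile describes these libraries and is not a p-value. The interval of a list median comes from the ranks of its members.

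The rule for named genes was also fixed then. Candidates had a symbol, at least 20 CPM in at least 1 of the 2 samples, at least 1 count in at least 20% of thinned cells in at least 1 of the 2, and the same direction in summed CPM, in the mean of per-cell CPM and in the share of thinned cells with a count, where a tie, or both shares at 95% or more, counts as the same. Of these, the 10 highest and 10 lowest were named in each comparison with DMSO, 5 and 5 in the comparisons with a single drug, and the 3 highest and 3 lowest departures from additivity. Of the genes picked in this way, 2 are not reported here. From each list up to 4 measured members with the largest absolute difference were open for naming, and always the drug targets and receptors, CYP26A1, DHRS3, RARB, MYCN, MKI67, CDKN1A and CDKN1B. The candidates numbered 3901, 4088 and 4519 against DMSO, 3628 for the combination against 13cRA and 4235 against doxazosin.

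For phase calls, shares and per-cell scores, each cell was thinned at random to 34000 counts, the 10th percentile of kept cells rounded down to 1000, and shallower cells were left out (25 DMSO, 69 13cRA, 4 doxazosin and 17 combination cells). Phases were called with scanpy score_genes_cell_cycle from the S and G2M lists on the 4 samples together. The per-cell score is the mean over list members of log2(CPM/10 + 1). Correlations of drug effects used 6711 genes with a symbol and at least 20 CPM in at least 1 of the 4 samples.

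Alternatives fixed before the data were examined were TMM factors, DESeq2 size factors, the mean of per-cell CPM, a pseudocount of 5 CPM, no cell filter, at least 2000 genes per cell, no filter on low genes for lists, at least 100 CPM for correlations, cells called G1 only, and unthinned counts. Alternatives chosen after seeing the data were leaving out cells over 9000 genes, subtracting the median of each of 20 GC bins, cells with 34000 to 120000 counts, and cells with 4000 to 4600 genes after thinning. The closing section gives their effect. A list of 12 nuclear-retained transcripts was also written after the data had been examined. What each window of cells selects was measured within each sample, as the list medians of its cells against all thinned cells.

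The comparison was tested on simulated data, in which 100 genes were changed 2-fold and 100 changed 4-fold among 5883 genes. In each of the 3 comparisons with DMSO all changed genes had the right sign. For the next figures the median of the genes known to be unchanged was first subtracted, which removes any common shift from scaling. The estimate then lay within 0.25 log2 of the truth for 100%, 100% and 99% of the genes changed 2-fold, in 13cRA, doxazosin and the combination. For those changed 4-fold the shares were 97%, 96% and 99%. No unchanged gene was off by 0.5 log2 or more. A planted list of 20 genes with a true log2 difference of 1 had medians of 0.96, 0.96 and 0.96 and lay above all 10000 random lists, and a list of 20 unchanged genes lay at percentiles 65.1, 59.1 and 55.1. The simulation covers counting, and scaling only in the signs, the unchanged genes and the lists. Its counts were Poisson draws from the summed DMSO counts, with no cells and no amplification of reads. Close recovery at 20 CPM or more was thus built in and does not bound the error of the real counts. Nor does the simulation cover the variation between samples, which these data cannot show.

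Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0; edgeR and DESeq2 gave scaling factors only. No sample and no cell column was left out other than by the cell filter.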

Results

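Single-cell RNA sequencing was carried out on CHP134, an established human neuroblastoma cell line with amplified MYCN, after 24 h of treatment. The cells received the vehicle DMSO at 0.04%, 13-cis retinoic acid (13cRA, isotretinoin) at 5 µM, doxazosin at 10 µM, or both drugs at these doses. 13cRA is a retinoid given to patients with neuroblastoma to induce differentiation, and doxazosin blocks α1-adrenergic receptors. Full-length libraries were made on 1 nanowell chip from 1 sample per treatment. The count table held 373 DMSO, 355 13cRA, 252 doxazosin and 307 combination cells, of which 353, 318, 239 and 287 passed the cell filter. Their summed counts were 48164169, 22636509, 46171287 and 72192743, in the same order. The median counts per kept cell were 122615, 59200, 171793 and 221558, so the 13cRA cells were the shallowest. At an equal 34000 counts per cell they also held the fewest genes, with a median of 3901 against 4678 in DMSO, 4769 in doxazosin and 4700 in the combination. With 1 sample per treatment, no difference below has a replicate error or a test. Levels are CPM (counts scaled to a total of 1e6) of the summed counts, and differences are log2 ratios of these levels. All intervals are 95% intervals. Those of a level cover counting error only, those of a share the sampling of cells, and those of a list median the spread between its members.

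The first comparison asks how 13cRA alone differed from the vehicle at 24 h. ENPP2, which encodes the secreted lysophospholipase autotaxin, stood farthest above DMSO, at 453 CPM (Poisson interval 444 to 462) in the 13cRA library against 1.64 CPM (1.3 to 2.04) in the DMSO library. SLIT2, an axon guidance ligand, was at 164 against 8.72 CPM, and RGS16, a regulator of G protein signalling, at 122 against 1.25 CPM. MFAP4, an extracellular matrix protein, was lower, at 117 CPM (112 to 121) against 817 CPM (809 to 825), as were STC1, a secreted glycoprotein hormone, at 44.3 against 252 CPM, and ISL1, a homeobox transcription factor of sympathetic neurons, at 11.9 against 54.4 CPM. FTH1, the ferritin heavy chain, was at 40.8 against 147 CPM. Among the highest named genes, 9 (ENPP2, RGS16, CCBE1, PLEKHA6, CCN3, NR0B1, RGS8, SLIT2 and BMF) had log2 differences from 3.50 to 7.43. The 10 lowest (MFAP4, PPP2R2B, STC1, DCLK3, FRZB, ISL1, SLC29A1, RELL1, MARCHF11 and FTH1) had values from −2.80 to −1.82.

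These differences rested on many cells. After thinning every cell to 34000 counts, ENPP2 had a count in 67.1% of 13cRA cells (exact binomial interval 60.9 to 72.9%) and 3.35% of DMSO cells (1.69 to 5.92%); without thinning the shares were 68.9% and 9.91%. For MFAP4 the thinned shares were 61.4% and 98.2%. In the annotation used here, GENCODE 29 on GRCh38, ENPP2 (ENSG00000136960.13, chromosome 8, 119557086 to 119673453), RGS16 (ENSG00000143333.7, chromosome 1, 182598623 to 182604408), SLIT2 (ENSG00000145147.20, chromosome 4, 20253260 to 20620561), MFAP4 (ENSG00000166482.12, chromosome 17, 19383442 to 19387240) and STC1 (ENSG00000159167.12, chromosome 8, 23841915 to 23854807) are protein-coding genes. That this build and release are those behind the deposited counts is not known. Scaling shifts the whole 13cRA library. The median log2 difference of all genes, meaning the 6423 with a symbol and at least 20 CPM in this comparison, was −0.047 with CPM. TMM factors moved it by −0.36, to −0.40, and DESeq2 size factors by −0.31, to −0.36. With these factors the median of all genes therefore lies farther from 0 than with CPM.

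**Figure D1:**
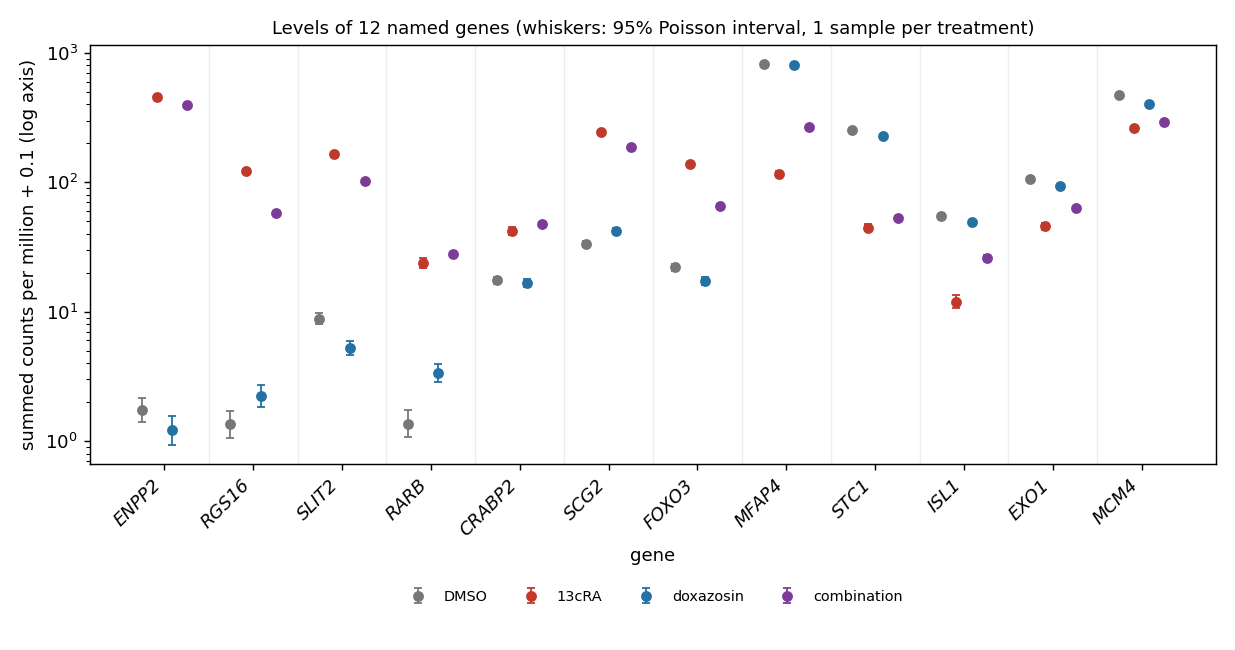
Levels of 12 named genes in the 4 libraries, in CPM plus 0.1 on a log axis, with exact 95% Poisson intervals (counting error only, 1 sample per treatment). ENPP2 lies at 453 and 395 CPM in the 2 libraries with 13cRA and at 1.64 and 1.13 CPM in the 2 without, and MFAP4 at 117 and 266 against 817 and 799.9 CPM.

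All 13 measured retinoid response genes were higher in the 13cRA library than in DMSO, with a median log2 difference of 0.70 (interval of the median 0.16 to 1.23, percentile 99.99 among 10000 random lists matched for level). With TMM factors and DESeq2 size factors 9 of the 13 were higher and 4 lower, with medians of 0.40 (−0.15 to 0.90) and 0.43 (−0.11 to 0.94). CRABP2, which delivers retinoic acid to its receptors, was at 42 against 17.4 CPM, the retinoic acid receptor gene RARB at 23.6 against 1.27 CPM, and NAV2 at 109.7 against 46 CPM. DHRS3, a retinaldehyde reductase, was low in every library, at 2.87 against 0.249 CPM, and CYP26A1, the main retinoic acid hydroxylase, had 0 counts in all 4 libraries, which allows at most 0.0623 CPM in DMSO, 0.133 in 13cRA, 0.065 in doxazosin and 0.0416 in the combination. Of 26 HOX genes on the list 5 were measured, and all 5 were higher (median 1.27, percentile 99.25), among them HOXC4 at 31.3 against 12.4 CPM and HOXD9 at 17.2 against 5 CPM. Only 3 reached 5 CPM in DMSO or doxazosin, so some of the 5 counted as measured only through the 13cRA library and had to be higher. The same holds for RARB in the retinoid list. Without the minimum of 5 CPM, 21 of 22 retinoid response genes were higher, with a median of 0.45. Relative to all genes, which TMM factors and DESeq2 size factors also shift, the retinoid response median was 0.80 and 0.80, against 0.75 with CPM. A scaling factor moves nearly all genes alike, so values relative to all genes barely depend on it. Here and below they are no separate check on a result. Beside these groups, mitochondrially encoded mRNAs were also higher in this library (median 0.65).

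Among neuronal differentiation genes, 21 of 33 were higher in the 13cRA library, with a median of 0.24 (−0.10 to 0.54, percentile 99.11), which was negative, −0.093 and −0.055, with TMM factors and DESeq2 size factors. Relative to the median of all genes it was 0.28, 0.31 and 0.31 under CPM, TMM and DESeq2 scaling, nearly equal by construction. Restricting to cells called G1 (43 13cRA and 16 DMSO cells), or to cells with 4000 to 4600 genes after thinning, gave −0.17 and −0.17 for this list, and ROBO2 was at −0.057 among cells with 34000 to 120000 counts. SCG2, a secretory granule protein, was at 245 against 33.4 CPM, the neurofilament gene NEFM at 455 against 159.6 CPM, the axon guidance receptor gene ROBO2 at 10.9 against 2.16 CPM and STMN4, a microtubule regulator, at 10.6 against 2.95 CPM. Of the members that were lower, the synaptic gene SNAP25 was at 12.4 against 29.4 CPM; it was picked after its values were seen. The per-cell score of this list, computed on thinned cells, had nearly equal medians, 1.56 in 13cRA and 1.59 in DMSO, and so differed in sign from the list median. The per-cell retinoid response score had medians of 0.79 (SD over cells 0.276) in 13cRA and 0.551 (0.214) in DMSO, and 81.5% of 13cRA cells lay above the DMSO median.

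Genes of DNA replication were lower in the 13cRA library: 39 of 42 measured S phase genes, with a median of −0.64 (interval of the median −0.73 to −0.52, below all 10000 random lists). MCM2, a subunit of the replicative helicase, was at 14.4 against 40.1 CPM, the nuclease EXO1 at 45.8 against 106 CPM, RRM2, a subunit of ribonucleotide reductase, at 243 against 488 CPM, and UNG, a uracil-DNA glycosylase, at 59.4 against 119 CPM. G2M phase genes were lower as well in 44 of 53 (median −0.33, percentile 0.10), with CKS1B at 207 against 415 CPM and CDC25C, a phosphatase that activates the mitotic kinase, at 12.1 against 24.9 CPM; MKI67 went the other way, at 158 against 96.3 CPM. Genes of G1 and cell cycle exit were higher in 12 of 16 (median 0.55, interval −0.065 to 1.41, percentile 99.89; 0.22 with TMM factors and 0.26 with DESeq2 size factors), led among well measured members by FOXO3, a forkhead transcription factor, at 139 against 22 CPM, and the stress-inducible gene GADD45A at 54.5 against 17 CPM. Relative to all genes the median of G1 and cell cycle exit genes was 0.62 with TMM factors and 0.62 with DESeq2 size factors, against 0.60 with CPM. The inhibitor genes CDKN1A and CDKN1B were at 49.9 against 73.1 CPM and 63.2 against 52.1 CPM. In this same library the mitochondrially encoded mRNAs were higher, with a median of 0.65. Among the 96 13cRA and 105 DMSO cells with 4000 to 4600 genes after thinning, a comparison added after seeing the data, the S phase median was −0.088 and the G2M median 0.10. Among cells with 34000 to 120000 counts the S phase median was −0.36. Both windows also shift the S phase list within a sample. Within 13cRA it was 0.34 higher among cells in the window of genes and 0.22 higher in that of counts than in all thinned cells. Within DMSO it was 0.15 and 0.069 lower. Whether these shifts come from phase, or from depth and complexity themselves, was not tested.

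Several other gene groups set the 13cRA library apart, and 1 of them is a measure of RNA composition. All 13 mitochondrially encoded mRNAs were higher than in DMSO (median 0.65, above all 10000 random lists, or 0.32 with TMM factors), for example MT-ND4 at 14629 against 8605 CPM and MT-CO2 at 15755 against 9483 CPM. The mitochondrially encoded ribosomal RNAs, added after their values were seen, did not follow, with MT-RNR2 at 40968 against 44289 CPM and MT-RNR1 at 8700 against 8063 CPM. Extracellular matrix and integrin genes were higher in 11 of 15 (median 0.73, percentile 99.88, or 0.41 with TMM factors), with the protease gene MMP11 at 43.8 against 3.53 CPM, the collagen gene COL5A1 at 21.9 against 6.23 CPM and COL6A1 at 17.1 against 5.61 CPM. COL6A1 had a log2 difference of −0.44 among cells with 4000 to 4600 genes after thinning. Immediate early and heat shock genes had a median of 0.34 (percentile 99.39), or 0.018 with TMM factors and −0.064 among cells with 4000 to 4600 genes after thinning, and included JUN at 44.4 against 6.27 CPM. Interferon response genes had a median of 0.45 over 6 genes (percentile 98.6), or 0.13 with TMM factors. TMM factors shift all genes here, so the medians were also taken relative to all genes, which takes most of the factor out again. For mitochondrially encoded, extracellular matrix, immediate early and interferon genes they were then 0.72, 0.81, 0.42 and 0.53 with TMM factors, against 0.70, 0.78, 0.39 and 0.50 with CPM. The intervals of the extracellular matrix, immediate early and interferon medians included 0 (−0.12 to 1.46, −0.050 to 0.79 and −0.45 to 1.56), and their per-cell scores did not rise, with 49.8%, 46.6% and 48.2% of 13cRA cells above the DMSO median. Cholesterol biosynthesis genes had a median of −0.29 (percentile 2.85), with HMGCS1, which makes HMG-CoA, at 84.1 against 198 CPM and the sterol carrier STARD4 at 14.9 against 42.2 CPM. Single members of other groups were lower: the serine synthesis gene PSAT1 at 55.6 against 171 CPM, the chaperone PDIA6 at 76.1 against 200.3 CPM, GAPDH at 1419 against 3482 CPM and the G1 kinase gene CDK4 at 137 against 344 CPM.

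The remaining lists had smaller medians in this comparison. They were −0.058 for noradrenergic identity, 0.14 for the mesenchymal state, −0.010 for p53 targets, −0.12 for apoptosis regulators, 0.011 for the unfolded protein and integrated stress response, 0.056 for lysosome and autophagy, −0.054 for MYC targets and ribosome biogenesis, −0.053 for oxidative phosphorylation and −0.19 for glycolysis and hypoxia. With TMM factors or DESeq2 size factors all 9 of these medians were negative, and relative to all genes those of the mesenchymal state, the stress response and the lysosome were 0.10, 0.090 and 0.13 with TMM factors. Per cell these lists lay lower than the sums show, in cells that also held the fewest genes: only 9.64% of 13cRA cells were above the DMSO median score for oxidative phosphorylation, 13.3% for the unfolded protein and integrated stress response, 24.1% for glycolysis and hypoxia, and 26.5% to 37.3% for the other 6. The drug targets and receptors had a median of 0.62 over 9 measured genes (−0.37 to 1.23, percentile 99.09), and MYCN was at 1168 against 759.6 CPM. The α1-adrenergic receptor genes ADRA1A, ADRA1B and ADRA1D did not exceed 0.152 CPM in any library. Markers of other cell types were scarce: no leukocyte or epithelial marker and 1 Schwann cell marker (ERBB3 at 6.54 against 0.166 CPM) reached 5 CPM in either library. The 3 fibroblast markers measured had a median of 0.61 (percentile 55.6), and of the 2 endothelial markers CLDN5 was at 19.7 against 0.54 CPM and EGFL7 at 1.06 against 5 CPM.

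**Figure D2:**
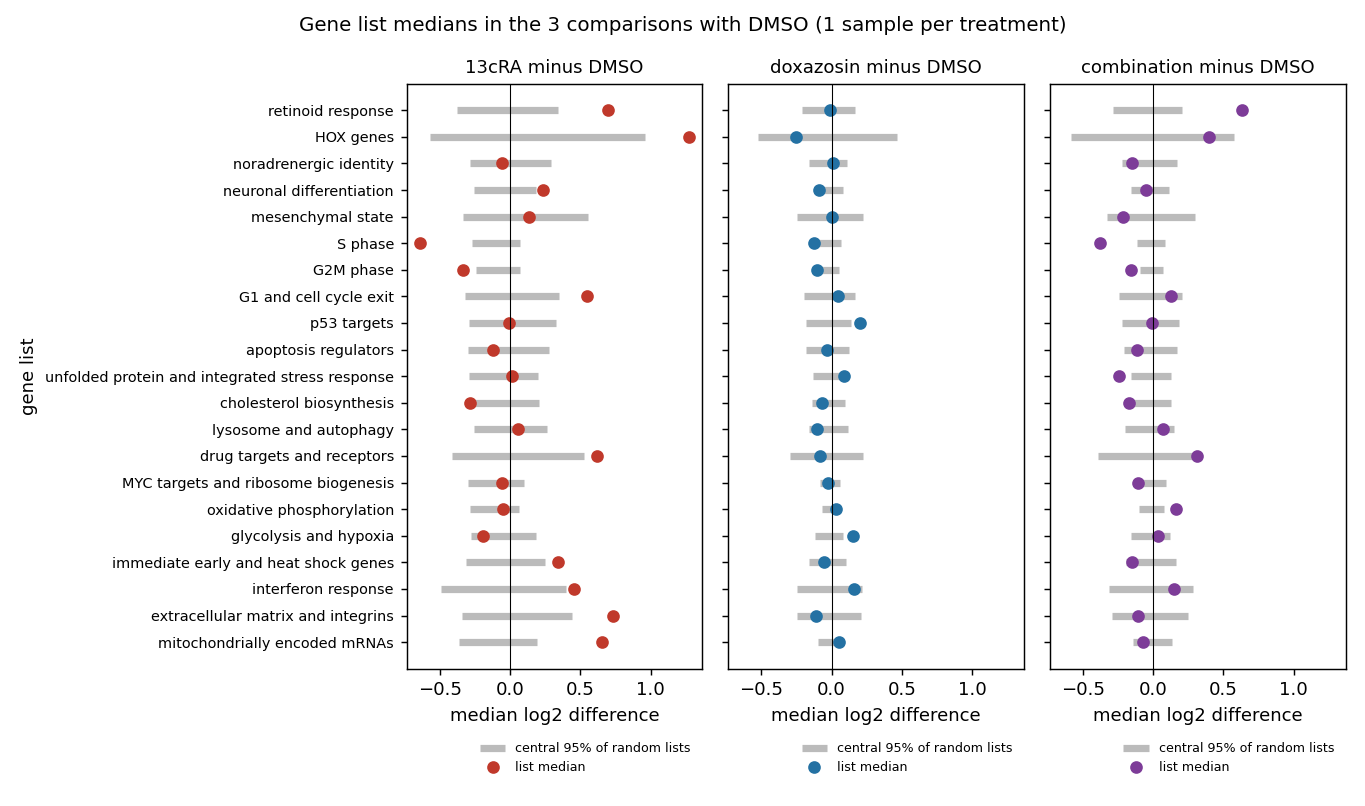
Median log2 difference of each fixed gene list (points) in the 3 comparisons with DMSO, with the central 95% range of 10000 random lists of the same size matched for level (lines). The retinoid response lies at 0.70, −0.013 and 0.63 in 13cRA, doxazosin and the combination, and the S phase list at −0.64, −0.13 and −0.38. Under TMM or DESeq2 scaling the neuronal differentiation value of 13cRA is negative. Relative to all genes it is 0.31, a value that a scaling factor common to all genes barely changes.

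Doxazosin alone was compared with the vehicle to show the effect of the second drug by itself. Its library lay nearer to DMSO, with a median absolute log2 difference of 0.16 over 6144 genes, against 0.35 over 6423 genes for 13cRA. The larger value goes with the shallow 13cRA library, since it was 0.34 in the combination against 13cRA and 0.20 in the combination against doxazosin. SLC35B3, which carries the sulfate donor PAPS into the Golgi, was at 34 CPM (32.3 to 35.7) in the doxazosin library against 10.6 CPM (9.69 to 11.5), and CBR4, a mitochondrial reductase of fatty acid synthesis, at 98.5 against 47.2 CPM. PGF, placental growth factor, was lower, at 9.79 CPM (8.91 to 10.7) against 24.3 CPM (23 to 25.8), as was PGLS, an enzyme of the pentose phosphate pathway, at 18.5 against 38.7 CPM. The 10 highest named genes (SLC35B3, TRIM23, UBN1, RINT1, RIC8B, TMEM150A, CBR4, SCML1, SYT11 and DIPK2A) had log2 differences from 0.99 to 1.59. Values from −1.23 to −0.90 belonged to 9 of the lowest (PGF, TEDC2, FBXL15, PGLS, KLHL18, TMEM39A, ST3GAL4, PAGE1 and THBS3). The shares of thinned cells with a count differed less than the sums. For SLC35B3 they were 25.1% (19.7 to 31.2%) against 19.5% (15.4 to 24.2%), with intervals that overlap. For PGF they were 19.6% (14.7 to 25.2%) against 33.8% (28.7 to 39.2%). SLC35B3 (ENSG00000124786.12, chromosome 6, 8411463 to 8435611) and PGF (ENSG00000119630.14, chromosome 14, 74941834 to 74955784) are protein-coding genes in the annotation used.

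By gene group, glycolysis and hypoxia genes were higher in the doxazosin library in 20 of 25 (median 0.15, percentile 99.98). Among them were BNIP3, a mitophagy receptor, at 99.5 against 66.8 CPM, and the aldolase gene ALDOC at 101 against 70.5 CPM. The p53 targets had a median of 0.20 over 20 genes (interval −0.16 to 0.47, percentile 99.58), with SESN1, a stress-inducible sestrin, at 14 against 5.17 CPM, PLK2 at 21.6 against 7.6 CPM, RRM2B, the p53-inducible ribonucleotide reductase subunit, at 15.9 against 6.02 CPM, and CDKN1A at 86.4 against 73.1 CPM; FAS was lower, on at most 2.55% of thinned cells. S phase genes were lower in 33 of 43 (median −0.13, percentile 0.21), with SLBP, which binds histone mRNA, at 44.1 against 60.3 CPM and TYMS, thymidylate synthase, at 16.9 against 22.4 CPM, and G2M genes in 36 of 53 (median −0.10, percentile 0.30), with KIF2C at 94.7 against 129 CPM. The per-cell G2M score differed in sign from that median, with 56.2% of doxazosin cells above the DMSO median, and for S phase the share was 48.9%. SLC6A2, the noradrenaline transporter gene, was at 2.4 against 6.23 CPM. The retinoid response list had a median of −0.013, with 6 of 12 genes higher.

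Medians of the other lists in doxazosin against DMSO were 0.091 for the unfolded protein and integrated stress response (percentile 96.4), −0.26 for HOX genes, 0.010 for noradrenergic identity, −0.091 for neuronal differentiation, 0.0047 for the mesenchymal state, 0.044 for G1 and cell cycle exit, −0.030 for apoptosis regulators and −0.069 for cholesterol biosynthesis. They were −0.10 for lysosome and autophagy, −0.085 for drug targets and receptors, −0.027 for MYC targets, 0.034 for oxidative phosphorylation, −0.055 for immediate early and heat shock genes, 0.16 for the interferon response, −0.11 for extracellular matrix and 0.050 for mitochondrially encoded mRNAs. Differences in this comparison followed the GC content of the genes: across 6711 genes, which are not independent replicates, Spearman's rho was −0.375. The trend gave a median log2 difference of 0.09 in the lowest and −0.16 in the highest of 5 bins of GC content. The 58 doxazosin and 141 DMSO cells with 34000 to 120000 counts gave a median of −0.0088 for S phase, 0.11 for G2M and −0.21 for p53 targets. This window shifts the cell cycle lists within a sample, with the G2M list 0.34 higher within doxazosin and 0.08 higher within DMSO than in all thinned cells. In these cells 5 named genes were lower, not higher, than in DMSO: PLK2 (−0.90), SESN1 (−0.88), RRM2B (−0.020), TMEM150A (−0.41) and UBN1 (−0.27). Cells with 4000 to 4600 genes after thinning moved the cell cycle lists the other way, with −0.35 for S phase and −0.17 for G2M, in a window whose S phase list was 0.42 lower within doxazosin and 0.15 lower within DMSO. They gave −0.21 for p53 targets, −2.14 for PLK2, −0.34 for SESN1, −0.70 for RINT1 and −0.037 for TMEM150A. The 17 doxazosin and 16 DMSO cells called G1 gave −1.37 for p53 targets.

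The combination was compared with DMSO to describe cells given both drugs. Genes high in 13cRA stood high here too: ENPP2 was at 395 CPM (391 to 400.0), SLIT2 at 102 CPM and RARB at 27.6 CPM. PRKCH, a protein kinase C gene, was at 23.3 against 1.1 CPM, and SPP1, the secreted phosphoprotein osteopontin, at 40.5 against 0.436 CPM. HTR3A, a serotonin-gated channel subunit, was lower, at 11.5 against 54.2 CPM, as were STC1 at 53 against 252 CPM, the aggrecanase gene ADAMTS5 at 14.2 against 53.2 CPM and ID1 at 35.3 against 125 CPM. The 10 highest named genes (ENPP2, CCBE1, SPP1, RGS16, CCN3, PLEKHA6, NR0B1, PALMD, RARB and PRKCH) had log2 differences from 3.53 to 7.23, and the 10 lowest (DCLK3, STC1, HTR3A, SMCO4, ADAMTS5, ID1, PPP2R2B, CNTNAP2, ZNF521 and MFAP4) from −3.35 to −1.61. The median absolute log2 difference was 0.21 over 6239 genes. Differences followed GC content here too (rho −0.25 across 6711 genes).

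Retinoid response genes were higher in the combination than in DMSO in 11 of 13 (median 0.63, interval 0.019 to 1.41, above all 10000 random lists), and all 5 measured HOX genes were higher (median 0.40, percentile 92.8). Some of these HOX genes again reached 5 CPM only in the treated library and had to be higher. The per-cell retinoid response score had a median of 0.878 (SD over cells 0.243), and 93.7% of cells lay above the DMSO median. S phase genes were lower in 38 of 42 (median −0.38, below all 10000 random lists), with EXO1 at 62.7 against 106 CPM and MCM4 at 293 against 473 CPM, and G2M genes were lower in 40 of 53 (median −0.16, percentile 0.06). Genes of the unfolded protein and integrated stress response had a median of −0.24 (percentile 0.18), with PDIA6 at 108 against 200.3 CPM and SDF2L1, an endoplasmic reticulum protein, at 13.2 against 30.6 CPM. Oxidative phosphorylation genes were higher in 28 of 39 (median 0.16, above all 10000 random lists). SCG2 was at 189 against 33.4 CPM and CRMP1 at 507 against 247 CPM, while the neuronal differentiation list as a whole had a median of −0.054 and mitochondrially encoded mRNAs −0.072. The other medians were −0.15 for noradrenergic identity, −0.21 for the mesenchymal state, 0.13 for G1 and cell cycle exit, −0.010 for p53 targets, −0.11 for apoptosis regulators, −0.17 for cholesterol biosynthesis, 0.072 for lysosome and autophagy and 0.31 for drug targets. They were −0.11 for MYC targets, 0.036 for glycolysis and hypoxia, −0.15 for immediate early genes, 0.15 for the interferon response and −0.11 for extracellular matrix. Among the 38 combination and 141 DMSO cells with 34000 to 120000 counts, the S phase median was −0.083 and the G2M median −0.013. Within the combination this window had an S phase list 0.20 and a G2M list 0.22 higher than all thinned cells, against 0.069 lower and 0.08 higher within DMSO. Among cells with 4000 to 4600 genes after thinning the medians were −0.71 and −0.52, and there the S phase list was 0.53 lower within the combination and 0.15 lower within DMSO.

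Phase calls, made on thinned cells from the S and G2M lists, put 48.2% of DMSO cells in S phase (158 of 328 cells, exact binomial interval 42.6 to 53.7%), 26.9% of 13cRA cells (67 of 249, 21.5 to 32.9%), 41.3% of doxazosin cells (97 of 235, 34.9 to 47.9%) and 31.5% of combination cells (85 of 270, 26.0 to 37.4%). The shares called G1 were 4.88% (2.81 to 7.80%), 17.3% (12.8 to 22.5%), 7.23% (4.27 to 11.3%) and 14.8% (10.8 to 19.6%), and those called G2M were 47.0%, 55.8%, 51.5% and 53.7%. The calls are relative to the other cells and to low per-cell depth, so they are read beside the list medians and not as measured cycling. For G2M they point opposite ways. Each treated sample had a higher share called G2M than DMSO, but a lower list median (−0.33 in 13cRA, −0.10 in doxazosin, −0.16 in the combination). Only 29.7% of 13cRA cells lay above the DMSO median of the per-cell G2M score. Without thinning the S phase shares were 42.5%, 20.1%, 36.0% and 30.0%, those called G1 were 3.12%, 9.75%, 3.77% and 6.97%, and those called G2M were 54.4%, 70.1%, 60.3% and 63.1%.

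**Figure D3:**
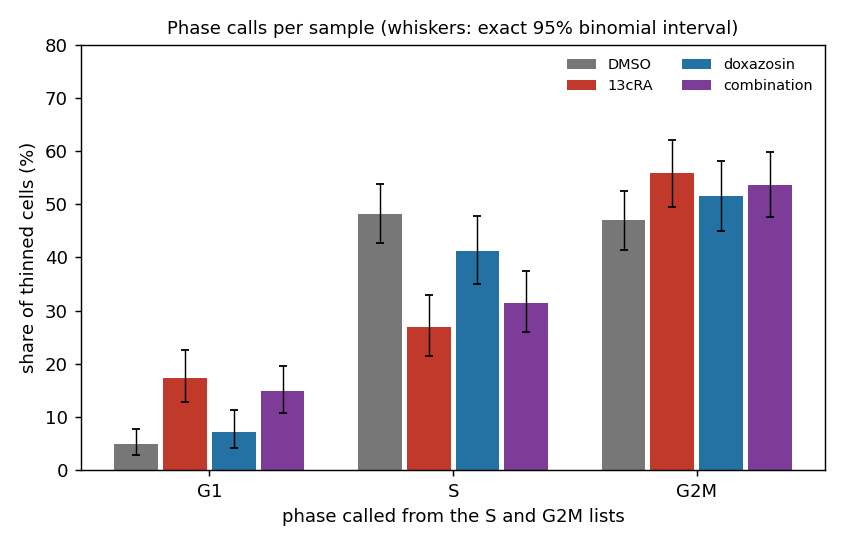
Share of thinned cells called G1, S or G2M in each of the 4 samples, in percent, with exact 95% binomial intervals (counting error only). The S phase share is 48.2% in DMSO, 26.9% in 13cRA, 41.3% in doxazosin and 31.5% in the combination.

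Adding doxazosin to 13cRA was examined by setting the combination against 13cRA alone. CTH, the enzyme that makes cysteine from cystathionine, was higher with both drugs, at 35.6 against 8.75 CPM, as were the replication gene MCM2 at 36.9 against 14.4 CPM, CDK4 at 308 against 137 CPM and SNAP25 at 37.6 against 12.4 CPM. SMO, the Hedgehog signal transducer, was lower, at 12 against 49.6 CPM, as were PIM3, a serine/threonine kinase gene, at 5.76 against 26.8 CPM, and KLF13 at 11.2 against 43.6 CPM. The 5 highest named genes were CKMT2-AS1, LINC02525, CTH, DIS3L and SCAMP1-AS1 (log2 1.84 to 2.07), and the 5 lowest PIM3, SMO, PMEPA1, ANKRD36C and KLF13 (−2.04 to −1.87). Antisense genes and near-identical paralogs among them are uncertain, because neither the strandedness of the counting nor its treatment of shared reads is known. S phase genes had a median of 0.28 (percentile 99.28), or 0.22 relative to all genes with TMM factors, which moved the median of all genes here by 0.33 (DESeq2 size factors by 0.26). Mitochondrially encoded mRNAs had a median of −0.68 (below all 10000 random lists), immediate early and heat shock genes −0.42 (percentile 0.23), noradrenergic identity genes −0.42 (percentile 0.27) and G1 and cell cycle exit genes −0.34 (percentile 2.09), with FOXO3 at 65 against 139 CPM and EGR1, an immediate early transcription factor, at 6.91 against 23.1 CPM. With TMM factors the last 3 of these medians were −0.12, −0.13 and −0.042, with intervals that include 0. Relative to all genes, where the factor largely cancels, they were −0.49, −0.50 and −0.41, against −0.46, −0.46 and −0.38 with CPM. The retinoid response median was 0.065 (percentile 67.3). This comparison sets the deepest cells against the shallowest. Its differences also followed GC content (rho −0.22 across 6711 genes). Among cells with 4000 to 4600 genes after thinning the S phase median was −0.64, the G1 and cell cycle exit median 0.15, and the difference of FOXO3 0.038. That window shifts the S phase list in opposite directions, 0.34 higher within 13cRA and 0.53 lower within the combination than in all thinned cells. Among cells with 34000 to 120000 counts the S phase median was 0.26.

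The combination against doxazosin alone shows 13cRA on the doxazosin background, between the libraries with the deepest cells. The 5 highest named genes were ENPP2, CCBE1, SPP1, RGS16 and PRKCH (log2 4.22 to 7.54), and the 5 lowest ADAMTS5, STC1, HTR3A, MBNL3 and DIPK2A (−2.16 to −1.68). Retinoid response genes were higher in 10 of 13 (median 0.82, interval −0.074 to 1.47, above all 10000 random lists), with CRABP2 at 47.8 against 16.6 CPM and the receptor gene RARG at 15.2 against 5.54 CPM, and HOX genes had a median of 0.93 (percentile 99.66). S phase genes had a median of −0.29 (below all 10000 random lists), with 36 of 43 lower, and G2M genes −0.10 (percentile 1.47). The unfolded protein and integrated stress response had a median of −0.37 (below all 10000 random lists), oxidative phosphorylation 0.12 (percentile 99.99, or 0.024 with DESeq2 size factors) and mitochondrially encoded mRNAs −0.046 (percentile 26.3). DESeq2 size factors shift all genes here by −0.099, and relative to all genes oxidative phosphorylation was at 0.13 with them and 0.13 with CPM. Among the 38 combination and 58 doxazosin cells with 34000 to 120000 counts, CRABP2 was at −0.19 and the oxidative phosphorylation median was −0.046.

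Across 6711 genes, the 13cRA difference measured against DMSO and that measured against doxazosin, which share no library, had a Pearson r of 0.553 and a Spearman rho of 0.386, with a slope of 0.43. The doxazosin difference measured against DMSO and that measured against 13cRA had an r of 0.267 and a rho of 0.296. Genes are not independent replicates, so these 2 correlations describe the libraries and have no p-value. Departures from additivity, the combination minus both single drugs plus DMSO on the log2 scale, were highest for CKMT2-AS1 (2.16), SCAMP1-AS1 (2.02) and DIS3L (1.86), and lowest for ANKRD36C (−2.43), PCDH9 (−2.18) and ATF3 (−2.10). Chosen after their values were seen, ENPP2 and MFAP4 stand beside these: for ENPP2 the departure was 0.12 and for MFAP4 1.21. Among lists, it was −0.72 for mitochondrially encoded mRNAs, 0.37 for S phase, 0.25 for G2M, −0.46 for noradrenergic identity and −0.40 for immediate early and heat shock genes, beside a shift of all genes by 0.30 with TMM factors and 0.20 with DESeq2 size factors. Among cells with 4000 to 4600 genes after thinning the S phase and G2M departures were −0.24 and −0.40, and among cells with 34000 to 120000 counts that of PCDH9 was 0.87.

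**Figure D4:**
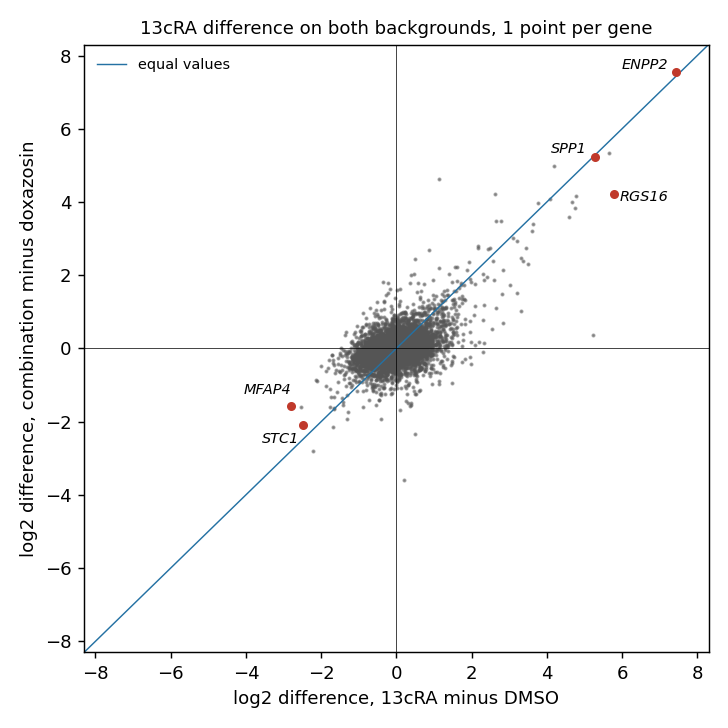
Log2 difference of 6711 genes in 13cRA against DMSO (horizontal axis) and in the combination against doxazosin (vertical axis), each point a gene, with the line of equal values. Pearson's r is 0.553 across genes, which are not independent replicates, and ENPP2 lies at 7.43 and 7.54.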

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

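Among the tests below, those that use the combination against doxazosin and the ribosomal RNAs for the mitochondrially encoded mRNAs, and the window of counts for the S phase list of the combination, were chosen after the result was seen; the cell windows and the removal of the GC trend were settings added after seeing the data, and the class of nuclear-retained transcripts was picked after single members of that kind had been seen high in the 13cRA library.

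The results here are those in which a drug's difference pointed one way without the other drug and the opposite way with it. Each side rests on 1 sample per treatment, so these differences were not tested, and the size limits (0.5 on the log2 scale each way for genes and 0.1 for lists) were chosen after seeing the data. For 13cRA, without and then with doxazosin, the log2 differences were −0.88 and 0.98 for DIS3L, 1.17 and −0.67 for HSPA1B, −0.79 and 2.45 for MAML2, 0.72 and −0.73 for SESN1, and 0.67 and −0.69 for VEGFA. The list medians were 0.14 and −0.11 for the mesenchymal state and 0.34 and −0.14 for immediate early and heat shock genes. For doxazosin, without and then with 13cRA, the values were 0.55 and −1.88 for ANKRD36C, 0.53 and −1.57 for ATF3, −0.65 and 0.86 for CDCA2, −0.56 and 0.82 for CHGB, 0.61 and −1.09 for DDIT3, 0.99 and −0.79 for DIPK2A and −0.52 and 0.68 for FLCN. They were 0.57 and −0.54 for KCNH2, 1.40 and −0.63 for PLK2, 1.08 and −0.70 for TMEM150A and 0.56 and −0.79 for VEGFA. The list medians were −0.13 and 0.28 for S phase, −0.10 and 0.19 for G2M and −0.10 and 0.12 for lysosome and autophagy. Most of these 21 results depend on which cells are compared: the opposite directions were kept in 8 among cells with 34000 to 120000 counts, in 4 among cells with 4000 to 4600 genes after thinning, and in both only for DIPK2A. With TMM factors and with DESeq2 size factors 20 of the 21 were kept. The mesenchymal state was not, since its 13cRA value without doxazosin was −0.30 and −0.26, and for immediate early and heat shock genes that value fell to 0.018 and 0.056. These factors move all genes of that comparison by −0.36 and −0.31. Relative to all genes, where the factor largely cancels, the values were 0.10 and 0.098 for the mesenchymal state and 0.42 and 0.42 for immediate early and heat shock genes. In these windows the doxazosin value without 13cRA was −0.90 and −2.14 for PLK2 and −0.41 and −0.037 for TMEM150A, and for S phase the value with 13cRA was 0.26 and −0.64. The windows hold few cells and also shift the cell cycle lists within a sample, so they do not settle the direction. HSPA1B and ANKRD36C have near-identical paralogs, and MAML2 had a count in at most 3.70% of thinned cells in any library.

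In the 13cRA library alone, all 13 mitochondrially encoded mRNAs were higher than in DMSO (median 0.65). Shallower cells as the whole cause are argued against, since among cells with 34000 to 120000 counts the median was 0.67 (0.61 to 0.79), no smaller. That window narrows the difference in depth but does not make the 2 samples equal. A 13cRA effect that doxazosin leaves as it is would have shown in the combination against doxazosin, where the median was −0.046 (−0.14 to −0.015). Less complex cells cannot be told apart from the treatment, because among cells with 4000 to 4600 genes after thinning the median was 0.36 (0.29 to 0.44), smaller but not gone. That window also picks on these mRNAs, which were 0.16 lower within 13cRA and 0.15 higher within DMSO than in all thinned cells. A lower share of cytoplasmic RNA as the whole cause would raise the ribosomal RNAs of the mitochondria as well, but MT-RNR2 had a log2 difference of −0.11 and MT-RNR1 one of 0.11. These RNAs were chosen after their values were seen, and how well the libraries capture them against mRNAs is not known, so they do not settle this. In the same library 11 of 12 nuclear-retained transcripts were higher (median 0.95), a class picked because members had been seen high there, so this adds no test. Whether the mRNAs rose through the drug or through the handling of 1 suspension stays open, since the sample and the treatment are the same thing here.

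In the doxazosin library, differences from DMSO followed GC content (rho −0.375). Greater depth of its cells is argued against, because setting the deepest 109 DMSO cells against the shallowest 109 gave a rho of 0.014, and the same contrast within the 4 samples ran from −0.092 to 0.115. With the trend removed, the glycolysis and hypoxia median was 0.23 (0.12 to 0.34, percentile 100) and the S phase median −0.18 (−0.22 to −0.13, percentile 0). The trend itself had a median of −0.12 (−0.14 to −0.0335) over the first list and 0.039 (−0.00041 to 0.061) over the second. Each is opposite in sign to its list median, so removing the trend could only enlarge that median. The trend does not account for either list. The p53 target median went from 0.20 to 0.19 (percentile 99.46, and 99.31 to 99.60 over the random draws). Over these genes the trend had a median of −0.0335 (−0.12 to 0.039), so it is not the whole of the p53 target median. The interval of that list median included 0 before (−0.16 to 0.47) and after (−0.085 to 0.45). Among cells with 34000 to 120000 counts it was −0.21, so whether the list as a whole is higher stays open for reasons other than GC content. The source of the trend itself, drug or library, was not tested.

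S phase genes were lower than in DMSO in both libraries with 13cRA, with medians of −0.64 and, in the combination, −0.38. For the combination, the greater depth of its cells cannot be told apart from the treatment by the window of counts. Among cells with 34000 to 120000 counts the median was −0.083 (−0.26 to −0.0099). That window also shifts the S phase list, which was 0.20 higher within the combination and 0.069 lower within DMSO than in all thinned cells. Whether phase or depth itself lies behind this shift was not tested. With every cell thinned to 34000 counts the difference remained. The median per-cell S phase score was 2.62 against 2.97 in DMSO, and 31.5% (26.0 to 37.4%) against 48.2% (42.6 to 53.7%) of cells were called S phase. Thinning makes the counts per cell equal but does not change which cells were deep. Among cells with 4000 to 4600 genes after thinning the median was −0.71 (−0.86 to −0.63), in a window where that list was 0.53 lower within the combination and 0.15 lower within DMSO. Against doxazosin the combination had a median of −0.29 (−0.37 to −0.21), which was −0.048 (−0.24 to 0.14) among cells with 34000 to 120000 counts and −0.37 (−0.51 to −0.12) among cells with 4000 to 4600 genes after thinning. For 13cRA alone, less complex cells cannot be told apart from a lower share of replicating cells. Among cells with 4000 to 4600 genes after thinning the median was −0.088 (−0.22 to 0.0056). That window also shifts this list: against all thinned cells it was higher within the 13cRA sample (0.34) and lower within DMSO (−0.15). Whether phase or complexity itself lies behind this shift was not tested. A 13cRA effect on the cell cycle therefore remains a hypothesis, which a count of cells in S phase by DNA labelling in replicate cultures would test.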

How the results depend on the processing

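Of the alternatives, the limit of 9000 genes, the removal of the GC trend and the windows of counts and of genes after thinning were chosen after seeing the data. In all, 250 reported results were recomputed under the alternatives that apply to each, which gave 2506 values, of which 29 were labelled reversed. That label leaves out other changes of sign. With TMM factors the 13cRA medians of the mesenchymal state (0.14 to −0.30) and of lysosome and autophagy (0.056 to −0.27) changed sign without it. The numbers of reversals that follow, 0 included, are therefore not counts of all changes of sign. Under the alternatives fixed beforehand, 557 values of single genes stayed within their counting interval, 325 moved beyond it and 0 reversed; for list medians the numbers were 562, 69 and 4. Under those added later they were 325, 249 and 14 for genes and 280, 32 and 11 for list medians. A correlation counted as moved beyond 0.05. The windows hold few cells (38 combination cells with 34000 to 120000 counts, 40 doxazosin cells with 4000 to 4600 genes after thinning, 16 DMSO cells called G1), and the depth of the 13cRA library, 22636509 counts, limits low genes most. Intervals of a summed count leave out the variation between cultures, which no alternative can show.

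With TMM factors the medians in 13cRA against DMSO were 0.40 for the retinoid response, −0.093 for neuronal differentiation, −0.97 for S phase and −0.67 for G2M, and with DESeq2 size factors 0.43, −0.055, −0.93 and −0.63, which follows from the shift of all genes by these scalings. With the mean of per-cell CPM, S phase was −0.48 in 13cRA, −0.040 in doxazosin and −0.29 in the combination, G2M in 13cRA was −0.19, and the correlations of the 13cRA and doxazosin differences were 0.65 and 0.39. At 100 CPM or more these correlations were 0.70 and 0.39. With the GC trend removed, S phase in doxazosin was −0.18 and the doxazosin correlation 0.20. In cells called G1, neuronal differentiation was −0.17 in 13cRA and −0.37 in doxazosin, and in doxazosin the retinoid response was −0.67 and p53 targets −1.37. For these and the values below, the cause was not tested.

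Among cells with 34000 to 120000 counts, S phase was −0.36 in 13cRA, −0.0088 in doxazosin and −0.083 in the combination, G2M was 0.11 in doxazosin and −0.013 in the combination, p53 targets in doxazosin were at −0.21, and the 13cRA correlation was 0.50. This window also shifts the cell cycle lists within a sample. Against all thinned cells of the same sample the S phase list was at −0.069 in DMSO, 0.22 in 13cRA, 0.030 in doxazosin and 0.20 in the combination. The G2M list was at 0.08, 0.15, 0.34 and 0.22. There, oxidative phosphorylation in the combination against doxazosin was −0.046, CRABP2 in that comparison −0.19, the departure of PCDH9 0.87, and in doxazosin RRM2B was −0.020, PLK2 −0.90, SESN1 −0.88, TMEM150A −0.41 and UBN1 −0.27. ROBO2 in 13cRA was −0.057. In the window of 4000 to 4600 genes after thinning the same values were −0.15, 0.34, −0.42 and −0.53 for S phase and −0.16, 0.29, −0.25 and −0.51 for G2M. Among its cells, the 13cRA medians were −0.17 for neuronal differentiation, −0.088 for S phase, 0.10 for G2M and −0.064 for immediate early and heat shock genes, and the 13cRA correlation was 0.32. In that window S phase was −0.35 and p53 targets −0.21 in doxazosin, S phase −0.71 and G2M −0.52 in the combination, and against 13cRA the combination had −0.64 for S phase, 0.15 for G1 and cell cycle exit and 0.038 for FOXO3. The departures there were −0.24 for S phase and −0.40 for G2M, and in doxazosin PLK2 was −2.14, RINT1 −0.70, SESN1 −0.34 and TMEM150A −0.037. COL6A1 in 13cRA was −0.44. The S phase share was 42.5% in DMSO and 20.1% in 13cRA without thinning, 40.2% in DMSO without the cell filter and 20.7% in 13cRA with at least 2000 genes per cell. The share called G1 fell without thinning to 9.75% in 13cRA, 3.77% in doxazosin and 6.97% in the combination, and that called G2M in 13cRA rose to 70.1%.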

Other observations

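No test is used here, and the list of nuclear-retained transcripts was written after the data had been examined.

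The most abundant transcript in every library was DDX1, the neighbour of MYCN on chromosome 2, at 5.34% of counts in DMSO, 4.80% in 13cRA, 5.34% in doxazosin and 5.53% in the combination. STMN1, a microtubule regulator, made up 0.777%, 0.90%, 0.872% and 1.27% of counts, in the same order. Among genes named by the fixed rule that the comparisons above did not describe, EGLN3, a prolyl hydroxylase that targets hypoxia-inducible factors, was at 3.24, 24, 3.01 and 19.9 CPM. SOX9, a transcription factor of neural crest and glia, was at 1.31, 27, 0.476 and 12.6 CPM. GATA2, a transcription factor of sympathetic precursors, was at 13.4, 6.58, 11.1 and 2.92 CPM, and DLK1, a relative of the Notch ligands, at 8.43, 2.34, 19.97 and 3.88 CPM. TP53INP1, a p53 target, was at 16.8, 33.9, 23.6 and 66.8 CPM.

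Among the 12 nuclear-retained transcripts, PNISR was at 145 CPM in DMSO, 304 in 13cRA, 132 in doxazosin and 167 in the combination, and LUC7L3 at 287, 552, 264 and 304 CPM. The list median was 0.95 in 13cRA, 0.057 in doxazosin and 0.19 in the combination, each against DMSO. The mitochondrially encoded ribosomal RNA MT-RNR2 was at 44289, 40968, 47273 and 41171 CPM, in the order given above, and MT-RNR1 at 8063, 8700, 7235 and 6262 CPM. A 13cRA culture prepared a second time would show whether the nuclear-retained transcripts go with the drug.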
